A study of Saccharolobus islandicus with 45 samples.

How the data were processed

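Saccharolobus islandicus REY15A, an archaeon that grows aerobically in hot acid, was grown from single colonies as 15 independent cultures, synchronized in the cell cycle and sampled for total RNA at 2.5 h, 4 h and 6 h, which gave 45 libraries. Per the labels, flow cytometry showed the cultures to be enriched in M-G1 cells at 2.5 h, S cells at 4 h and G2 cells at 6 h, and the cultures were handled in 3 batches of 5 on different days. The batch of each culture was not used here. Each culture was sampled at every time point, so a fit with culture as a block also removes differences between batches that are equal at all 3 time points. It does not remove batch differences that change with time.

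Per the labels' protocols, the libraries came from a stranded total RNA kit with custom depletion of ribosomal RNA, were sequenced on an Illumina NextSeq instrument, and the reads were mapped with Bowtie 2 at default settings to the RefSeq chromosome of REY15A. The counting tool, its strand setting and the annotation release are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes and of near-identical copies cannot be assigned with certainty, and a change in such a gene could belong to its partner. The deposited table holds raw counts per annotated feature, whole numbers whose totals differ between libraries, and edgeR is named in the submitters' processing notes without a version. All 45 columns were matched to libraries by title, and 0 columns were left unused.

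The table has 2805 rows, 2754 with the prefix gene and 51 with the prefix rna, and 1 row has no count in any library. The prefix rna is read here as a non-coding RNA feature. The features carry RefSeq locus tags of REY15A and no gene names. The reference table of gene names used here describes another strain of the species, and 0 of the 2805 tags matched it. None of the 24 gene lists fixed before the data were examined (cell division, replication initiation, chromatin proteins, ribosomal proteins and others) could be matched to the table, so no list was counted or tested, and gene functions are not given. The rule for named genes, also fixed beforehand, took for each comparison the 6 largest rises and the 6 largest falls by fitted fold change among gene rows with an adjusted p below 0.05, an average log2 CPM of at least 4 and the same direction in at least 12 of the 15 cultures. With no names to give, the parts of that rule that depend on gene products were not applied, and 2 tags per direction are printed, the first 2 rises and the first 2 falls of 6 h against 2.5 h. Other genes are described as groups.

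Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr on the time groups and robust quasi-likelihood F tests, in 1 fit of all 45 libraries with time point as the only term. The filter kept 2569 rows, 2551 of them gene rows. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. A gene was assigned a peak at a time point when its tests against both other time points were called and both fitted differences were at least 1.5-fold in favour of that time point. Levels are CPM, counts divided by the TMM-scaled library size. The same steps were tested on simulated counts for 6 h against 2.5 h with 2569 rows: 98% of 100 genes changed 2-fold and 84% of 100 genes changed 1.5-fold were recovered, and 11 of 193 calls were false. The simulated counts were drawn independently, with as many rises as falls. They held no differences between cultures and no planned fall of the most abundant rows. These rates therefore need not hold for the real libraries.

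Culture numbers in the titles are shared between time points, and the labels state that the same 15 cultures were sampled, so the numbers pair the libraries by design. Same-numbered libraries had a mean correlation of their deviations from the time-point means of 0.198 between 2.5 h and 4 h, 0.238 between 4 h and 6 h and 0.0942 between 2.5 h and 6 h. Differently numbered libraries had mean correlations of -0.0129, -0.0131 and -0.00725. Between cultures the same-number values varied widely, with SDs of 0.334, 0.294 and 0.289 and lowest values of -0.688, -0.451 and -0.519. Among the libraries of the later time point, the one with the same number correlated best in only 5, 2 and 2 of 15 cultures. The pairing therefore rests mainly on the labels. The fit with culture as a block was run as an alternative. No pair of libraries of 1 time point agreed within sampling noise, since the smallest chi-square per degree of freedom over 105 pairs was 15.7 at 2.5 h, 23.7 at 4 h and 13.5 at 6 h, so all 45 libraries were kept as separate samples.

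Shares of counts and positions of libraries were compared between time points with exact 2-sided sign-flip tests on the 15 cultures, adjusted over the 3 comparisons. The position of a library was measured on the axis from the mean of the 2.5 h libraries to the mean of the 6 h libraries in log2 CPM, with the axis taken from the 14 other cultures. Correlations across libraries used 100000 permutations. For genes next to each other in the table (tested gene rows only, with the rows between them that were not tested skipped), 1000 shuffled orders gave the range expected by chance. Locus tags ascend along the table for 2550 gene rows, with 204 later tags placed between them, and this order was taken as the order along the chromosome. These steps used Python 3.11.15, scipy 1.17.1 and statsmodels 0.14.6.

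Alternatives fixed before the data were examined were the culture block, DESeq2 size factors, total counts without TMM, no filter on low counts, DESeq2 1.42.0, fits of only the 2 time points compared, a 2-fold minimum, omission of the rna rows, and omission of each culture in turn. Camera tests of the gene lists (limma 3.58.1) and their alternatives were planned and not run. Alternatives chosen after seeing the data were thinning of every library to the lowest total, thinning of the counts outside the 2 most abundant rna rows to the lowest such count, the share of these 2 rows as a covariate, omission of the 4 h libraries of cultures 20 and 21, of those of cultures 11 and 12, or of the 3 deepest libraries, and the block with numbers 11 and 12 exchanged at 4 h.

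Totals ranged from 8216793 to 91563362 counts per library. Because most counts fell in 2 rna rows, the counts outside them, 1236741 to 18276412 per library, set the precision for other genes. Intervals of PCR-amplified reads without molecular identifiers would cover counting error only, so the spread between cultures is given instead.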

Results

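The transcriptome of synchronized S. islandicus REY15A was measured in 15 cultures at 2.5 h, 4 h and 6 h, with 1 library per culture and time point. Total counts per library ranged from 8560471 to 25032432 at 2.5 h (median 15049901), from 8216793 to 91563362 at 4 h (median 20811209) and from 9308612 to 18222774 at 6 h (median 12979827). Of 2569 rows tested, 1553 (60.5%) varied over the 3 time points in the joint edgeR F test at an adjusted p below 0.05. The count was 791 after thinning of the counts outside the 2 most abundant rna rows, and 222 at a 2-fold minimum.

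Most counts came from 2 non-coding RNA rows that lie next to each other in the table, and their share fell late in the time course. These rows carry no names here, and the share may in part reflect how well ribosomal RNA was depleted. Together they held 76.05% ± 5.484 of all counts at 2.5 h, 73.48% ± 14.2 at 4 h and 52.72% ± 18.34 at 6 h (SD, n = 15 each). From 4 h to 6 h the share fell by 20.8 percentage points on average and was lower in 14 of 15 cultures (exact 2-sided sign-flip test, p = 0.000305, adjusted p = 0.000549), and from 2.5 h to 6 h it fell by 23.3 points and was lower in 13 of 15 cultures (p = 0.000366, adjusted p = 0.000549). From 2.5 h to 4 h it was lower in 6 of 15 cultures and the mean difference of -2.57 points was within the spread between cultures (p = 0.601, also after adjustment). Single libraries ranged widely, from 20.33% to 79.15% at 6 h and from 36.31% to 87.07% at 4 h. Counts outside these rows came to 1733181 to 5350576 per library at 2.5 h, 1236741 to 18276412 at 4 h and 2568684 to 13908415 at 6 h.

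**Figure D1:**
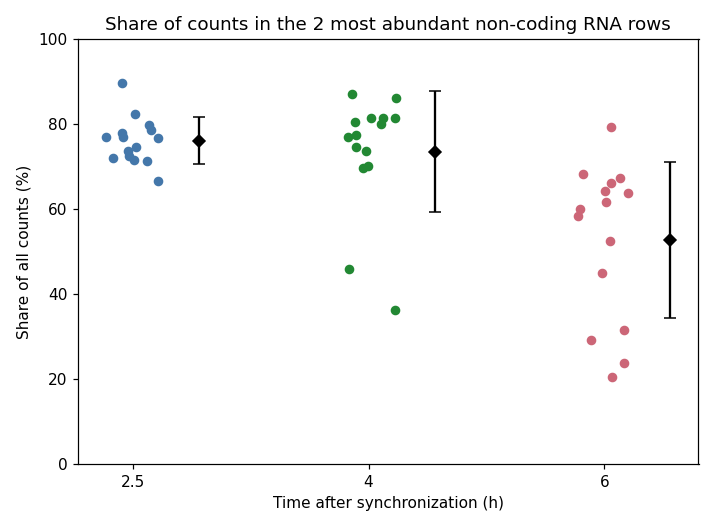
Share of all counts (percent) held by the 2 most abundant non-coding RNA rows in each library, by hours after synchronization. Points are the 15 cultures, and diamonds with bars are the mean and SD, which are 76.05% ± 5.484, 73.48% ± 14.2 and 52.72% ± 18.34.

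The fall of this share shifts the reference for other genes when libraries are scaled by total counts. With TMM scaling, the number of called rows changed little when the rna rows were left out. It was 817 against 814 for 4 h against 2.5 h, 704 against 709 for 6 h against 4 h and 1401 against 1395 for 6 h against 2.5 h. TMM scaling centres the median gene, and the median log2 change of all tested rows was 0.05 for 4 h against 2.5 h, -0.01 for 6 h against 4 h and 0.02 for 6 h against 2.5 h. With total counts as the only scaling, the medians were 0.19, 0.53 and 0.71, so the changes below are relative to the median gene and not to total RNA. On that relative scale, the 2 rows fell by 1.17 and 0.85 in log2 from 2.5 h to 6 h, with adjusted p of 0.000261 and 0.00409 in the edgeR fit and lower values in 13 of 15 cultures each.

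The comparison of 4 h with 2.5 h asks which transcripts changed between cultures enriched in M-G1 cells and cultures enriched in S cells. At 4 h, 814 rows (31.7%) were called, 468 higher and 346 lower. Most changes were small: the median absolute log2 change of the called rows was 0.473, and 57 rows changed at least 2-fold, 51 upward and 6 downward. The 6 largest rises under the rule for named genes were 2.31-fold to 3.69-fold and the 6 largest falls 2.0-fold to 4.38-fold, and 3 of these rises lay within 4 rows of another in the table. Runs of neighbouring genes rose together, the longest with 10 consecutive tested genes and a median log2 change of 0.86, and another with 8 genes and a median of 1.48. With total counts as the scaling, the comparison called 358 rows, 287 higher and 71 lower, and with the counts outside the 2 abundant rna rows thinned to 1236741 in every library it called 319.

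The comparison of 6 h with 4 h asks what changed between cultures enriched in S cells and cultures enriched in G2 cells. It called 709 rows (27.6%), 325 higher and 384 lower, with a median absolute log2 change of 0.461. A change of at least 2-fold was found for 14 rows upward and 30 downward. The rises were concentrated in abundant transcripts. Of the 638 gene rows with the highest expression, 163 rose and 44 fell, while of the 638 with the lowest expression 21 rose and 148 fell. Of the 100 most abundant gene rows, 37 rose and 4 fell, with a median log2 change of 0.266. The median of the former group lay above that of the latter by 0.323 in log2, and by 0.254 with total counts as the scaling. The 6 largest rises under the rule were 2.37-fold to 4.21-fold, and 5 of them lay within 4 rows of another. Those 5 belonged to a run of 8 adjacent genes that rose together, by 1.25 to 2.55 in log2. Of the 18 non-coding RNA rows, 6 fell and 12 were not called on the TMM scale, but with total counts as the scaling 5 rose and 4 fell. That scaling called 1597 rows in all, 1572 higher and 25 lower. Thinning to 1236741 counts outside the 2 abundant rows left 303 calls, omission of the 3 deepest libraries left 460, and with the share of those rows as a covariate only 246 of the 709 rows were among the 596 called.

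The comparison of 6 h with 2.5 h spans the sampled part of the cycle, from cultures enriched in M-G1 cells to cultures enriched in G2 cells. It called 1395 rows (54.3%), 753 higher and 642 lower, with a median absolute log2 change of 0.533, and 113 rows rose and 83 fell at least 2-fold. Of the 638 gene rows with the highest expression 271 rose and 108 fell, and of the 638 with the lowest 115 rose and 197 fell. Among the 18 non-coding RNA rows, 9 fell and 9 were not called on the TMM scale, while total counts as the scaling gave 4 rises and 3 falls. Among tested gene rows, the longest runs of neighbours were 11 consecutive genes that rose, with a median log2 change of 1.06, and 9 consecutive genes that fell, with a median of -0.738. With total counts as the scaling, 1976 rows were called, 1918 higher and 58 lower. The count was 837 with the share of the 2 abundant rows as a covariate, 650 of them among the 1395, and 786 after thinning to 1236741 counts outside those rows.

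**Figure D2:**
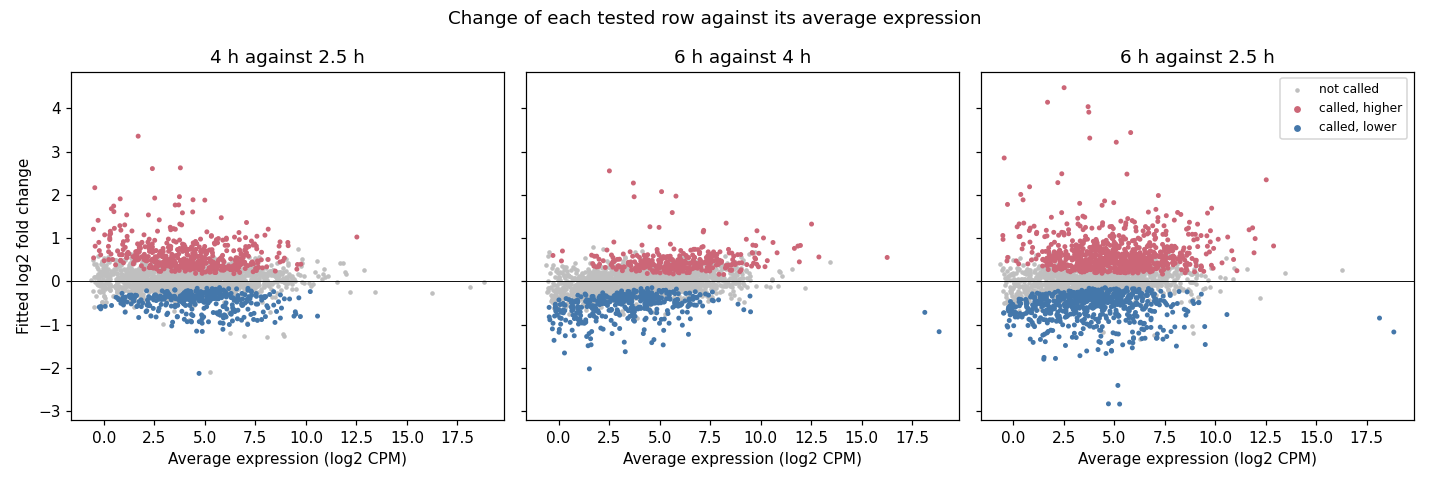
Fitted log2 fold change of each of the 2569 tested rows (vertical axis) against its average expression in log2 CPM (horizontal axis), for each comparison, with called rows coloured by direction. The called rows number 814, 709 and 1395, and in both comparisons with 6 h the 638 gene rows of highest expression hold more rises than falls (163 against 44 and 271 against 108).

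The largest rises under the rule were a pair of neighbouring genes. A gene row next to this pair did not meet the rule but rose more from 2.5 h to 6 h, by 4.04 in log2 (edgeR adjusted p = 2.37e-08). SIRE_RS07005 went from 11.43 ± 2.756 CPM at 2.5 h to 31.65 ± 26.04 at 4 h and 124.2 ± 140 at 6 h (SD, n = 15 each), with medians of 11.91, 20.7 and 61.59 CPM. The fitted change from 2.5 h to 6 h was 10.84-fold, a log2 change of 3.44 with a standard error of 0.4576 and an adjusted p of 5.252e-08 in edgeR, and it was upward in 14 of 15 cultures. With the culture block the log2 change was 2.57 (adjusted p = 1.15e-06), more than 1.5 times smaller as a fold. Its rise was called in both steps, by 1.47 in log2 from 2.5 h to 4 h (adjusted p = 0.008486) and by 1.97 from 4 h to 6 h (adjusted p = 0.0006643). The size of the rise differed between cultures, with 10.72 to 414.9 CPM at 6 h. SIRE_RS07000 rose alongside it, from 8.16 ± 1.886 to 17.95 ± 11.6 and 75.73 ± 80.85 CPM (SD, n = 15 each), 9.288-fold from 2.5 h to 6 h (log2 3.22, standard error 0.4124, adjusted p = 2.641e-08, upward in 14 of 15 cultures), and by 2.46 in log2 with the culture block (adjusted p = 8.091e-07). From 2.5 h to 4 h its adjusted p was 0.02273, and with the culture block 0.06451, which ends that call, as do 7 other settings with adjusted p from 0.0548 to 0.06621, among them the omission of culture 17 or 21, thinning and the omission of the 3 deepest libraries. Both genes belong to the run of 8 neighbours that rose from 4 h to 6 h. The share of the 2 abundant non-coding RNA rows fell in the same libraries, and with that share as a covariate the rises from 2.5 h to 6 h were still called but smaller, with log2 changes of 1.65 (adjusted p = 0.006471) for SIRE_RS07005 and 1.47 (adjusted p = 0.002872) for SIRE_RS07000. The changes from 2.5 h to 4 h were 1.49 and 1.14 with the covariate, both called, whereas those from 4 h to 6 h were not called, at 0.161 (standard error 0.4999, adjusted p = 0.8427) for SIRE_RS07005 and 0.326 (standard error 0.3992, adjusted p = 0.5807) for SIRE_RS07000.

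The largest falls were also a pair of neighbours, and they rested on a minority of cultures. SIRE_RS00350 averaged 83.83 ± 158.1 CPM at 2.5 h, 19.34 ± 57.33 at 4 h and 11.51 ± 29.55 at 6 h (SD, n = 15 each), but its medians were 7.08, 4.147 and 3.864 CPM. At 2.5 h it was above 100 CPM in 4 cultures (numbers 1, 3, 5 and 11, at 175, 334, 127 and 545 CPM) and at most 13.8 CPM in the other 11 cultures. The fitted fall from 2.5 h to 6 h was 7.155-fold (log2 -2.84, standard error 0.8682, adjusted p = 0.0059) and was downward in 15 of 15 cultures, with a log2 change of -2.07 in the fit with the culture block (adjusted p = 0.005694) and -3.72 without culture 11 (adjusted p = 0.0001854). The change from 2.5 h to 4 h lay at the threshold: it was not called in the edgeR fit without a block (log2 -2.09, adjusted p = 0.05169) and was called with the culture block (0.04241), with DESeq2 size factors (0.04732), with DESeq2's Wald test (0.01765) and without the rna rows (0.04983). Single cultures moved it several-fold, to a log2 change of -4.33 without culture 12 (adjusted p = 9.062e-05) and -1.29 without culture 11 (adjusted p = 0.1637). SIRE_RS00345 followed the same course, from 57.34 ± 101.7 to 12.84 ± 33.48 and 7.896 ± 17.25 CPM (SD, n = 15 each), with medians of 6.415, 3.559 and 3.206 CPM. Its fall from 2.5 h to 6 h was 7.128-fold (log2 -2.83, standard error 0.7813, adjusted p = 0.002418, downward in 15 of 15 cultures), and its log2 change was -2.05 with the culture block (adjusted p = 0.00294) and -3.43 without culture 11 (adjusted p = 0.0001337). Its fall from 2.5 h to 4 h was called (log2 -2.13, adjusted p = 0.02819) but lost the call without culture 1, 3 or 11, with adjusted p of 0.05286, 0.07032 and 0.09303, as it did without the 4 h libraries of cultures 20 and 21 (0.06165) and after thinning outside the 2 abundant rna rows (0.06829), while without culture 12 it was larger (log2 -3.92, adjusted p = 7.655e-05). Between 4 h and 6 h neither gene was called with all cultures (adjusted p = 0.5138 for SIRE_RS00350 and 0.496 for SIRE_RS00345). Without culture 11 both falls in that step were called (log2 -2.43, adjusted p = 0.01542, and log2 -2.01, adjusted p = 0.02583), and without culture 12 the fitted changes were upward and not called (log2 1.46 and 1.06). With the share of the 2 non-coding RNA rows as a covariate, the falls from 2.5 h to 6 h were no longer called: the log2 changes were -2.31 (standard error 1.193, adjusted p = 0.13) for SIRE_RS00350 and -2.40 (standard error 1.039, adjusted p = 0.07031) for SIRE_RS00345, with larger errors and smaller changes than without it.

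Genes that peaked at 1 time point by at least 1.5-fold were counted for that time point. Whether such a peak follows the cell-cycle phase or the time since synchronization was not tested. At 2.5 h 71 genes peaked, at 4 h 25 and at 6 h 61, with median fold differences over the next highest time point of 1.71, 1.63 and 1.65. At a 2-fold minimum, 6, 2 and 13 genes were left. Conversely, 141 genes were lowest at 2.5 h, 0 at 4 h and 80 at 6 h by the same criteria. The number of genes peaking at 4 h depended on single cultures: it was 13 with the culture block, and 10 without culture 12 or without culture 13, 11 without culture 4, 14 without culture 17 and 16 without culture 8. With total counts as the scaling, the peaks numbered 21, 4 and 912, and after thinning outside the 2 abundant rna rows 58, 4 and 39. With their share as a covariate 35 genes peaked at 6 h.

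The 4 h level was also placed relative to the other time points for the 1395 rows called between 2.5 h and 6 h, a choice of rows that by itself favours intermediate 4 h levels. Of these rows, 1066 (76.4%) had a fitted 4 h level between those of the other time points, 160 had passed the 6 h level and 169 lay on the far side of the 2.5 h level. The median row had made 52.7% of its change by 4 h, with an interquartile range of 25.7% to 78.8%. The position of whole libraries was measured on an axis taken from the other cultures. On this axis, scaled to 0 at the 2.5 h mean and 1 at the 6 h mean, the libraries lay at 0.0362 ± 0.192 at 2.5 h, 0.559 ± 0.329 at 4 h and 0.962 ± 0.276 at 6 h (SD, n = 15 each). All 15 cultures moved forward from 2.5 h to 4 h, by 0.523 on average (exact sign-flip test, p = 6.1e-05, the smallest this test can give, adjusted p = 9.15e-05), and 14 of 15 moved forward from 4 h to 6 h, by 0.403 (p = 0.000122, also after adjustment). The spread at 4 h was wide, from -0.0473 in the library numbered 12 to 1.15 in that of culture 20.

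**Figure D3:**
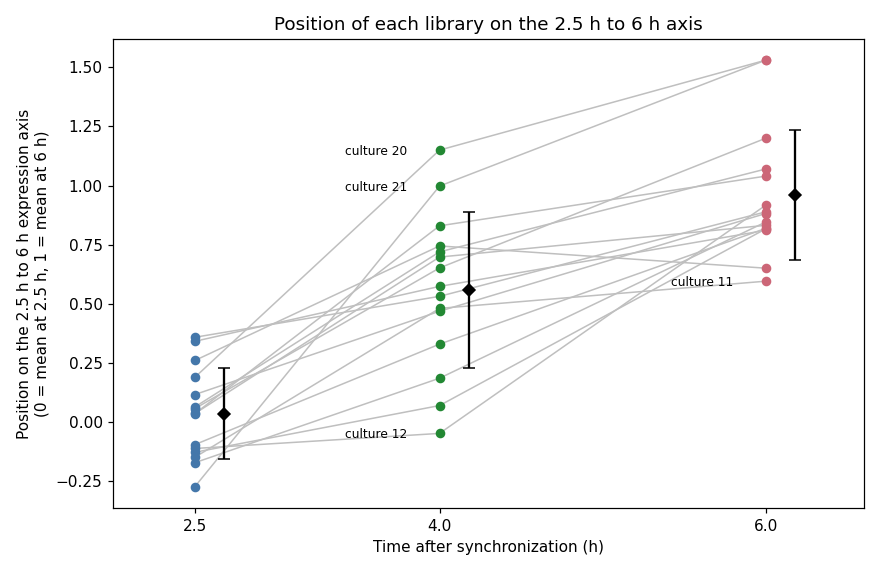
Position of each library on the expression axis from the 2.5 h mean (0) to the 6 h mean (1), by hours after synchronization, with grey lines joining the libraries of 1 culture and diamonds with bars for mean and SD. Means are 0.0362, 0.559 and 0.962, and the 4 h libraries spread from -0.0473 to 1.15.

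Genes that lie next to each other, with untested rows skipped, changed together in all 3 comparisons. Runs of at least 3 adjacent gene rows called in the same direction held 284 of 814 called gene rows for 4 h against 2.5 h, 163 of 703 for 6 h against 4 h and 686 of 1386 for 6 h against 2.5 h. In 1000 shuffled orders of the same calls, the highest numbers were 104, 70 and 340. Across genes, which are not independent replicates, the log2 changes of adjacent genes had a correlation of 0.492, 0.355 and 0.52 in the 3 comparisons. For 6 h against 2.5 h the correlation fell to 0.116 at 5 places apart, 0.0678 at 10 places, still above the 0.0412 that bounds 95% of shuffled orders, and 0.0213 at 20 places, within their range of -0.0389 to 0.0369. At 10 places it also lay above the shuffled range in the other comparisons, at 0.0852 for 4 h against 2.5 h and 0.0527 for 6 h against 4 h.

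**Figure D4:**
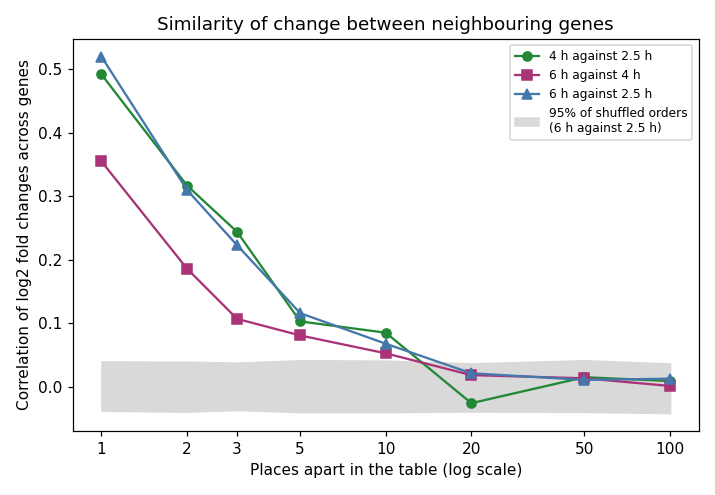
Correlation, across genes, of the log2 fold changes of genes that lie a given number of places apart in the table (horizontal axis, log scale), for each comparison. Grey marks 95% of shuffled orders for 6 h against 2.5 h, and the correlation of adjacent genes is 0.492, 0.355 and 0.52.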

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

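Of 554 values recomputed under 30 alternative settings, 487 kept their direction and their side of the threshold or stayed within 1.5 times the count given, 31 counts moved further, 17 values lost the call, 10 gained it and 9 changed sign. The planned camera tests of gene lists and their alternatives were not run, because the lists could not be matched to the table. Thinning, the covariate, the block with exchanged numbers and the omission of chosen 4 h libraries were picked after seeing the data. The cause of each difference below was not tested unless the setting itself gives it.

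With the replicate block, 839, 800 and 1422 rows were called for 4 h against 2.5 h, 6 h against 4 h and 6 h against 2.5 h, of which 737, 682 and 1341 were also called without it. The block with numbers 11 and 12 exchanged at 4 h gave the falls of SIRE_RS00350 and SIRE_RS00345 from 2.5 h to 4 h adjusted p of 0.001845 and 0.00044. The block as labelled moved the genes peaking at 4 h to 13 (13 also with the exchange), ended the call of SIRE_RS07000 and gave that of SIRE_RS00350 for 4 h against 2.5 h, and changed no other call of a named gene or count by over 1.5 times.

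Total counts as the only scaling called 358 rows for 4 h against 2.5 h and 1597 for 6 h against 4 h, and gave 21, 4 and 912 genes peaking at 2.5 h, 4 h and 6 h. A 2-fold minimum by its construction lowered the counts to 57, 44 and 196 in the 3 comparisons, to 222 over the 3 time points and to 6, 2 and 13 peaks. DESeq2's own test called 884, 804 and 1463 rows. Without each culture in turn, the counts ranged from 655 to 867, 584 to 734 and 1265 to 1406, the count over all time points from 1391 to 1577, and the peaks from 64 to 92 at 2.5 h, from 10 (culture 12 or 13) to 32 (culture 21) at 4 h and from 53 to 69 at 6 h.

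Thinned to 8216793 counts, 581, 537 and 1145 rows were called and 14 genes peaked at 4 h. Thinned to 1236741 counts outside the 2 abundant non-coding RNA rows, 319, 303 and 786 rows were called, 791 over the 3 time points, and 4 genes peaked at 4 h and 39 at 6 h. The 622 calls lost for 6 h against 2.5 h had a median absolute log2 change of 0.413, and the 773 kept 0.642, so depth limits the smaller changes. With the share of the 2 abundant non-coding RNA rows as a covariate, 837 rows were called for 6 h against 2.5 h (650 of them also called without it) and 35 genes peaked at 6 h. For 4 h against 2.5 h it called 960 rows, more than for 6 h against 2.5 h, the reverse of the order without it. For 6 h against 4 h the covariate called 596 rows, of which 246 were also called without it. Without the 4 h libraries of cultures 20 and 21, 671, 866 and 1437 rows were called. Without the 4 h libraries of cultures 11 and 12, 10 genes peaked at 4 h. Without the 3 deepest libraries, all at 4 h, 460 rows were called for 6 h against 4 h and 5 genes peaked at 4 h.

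The changes of sign all concerned 6 h against 4 h in the pair of falling genes, which was not called with all libraries. For SIRE_RS00350 the log2 change became 0.4907 with total counts, 0.08601 with the covariate, 1.392 without the 4 h libraries of cultures 11 and 12 and 1.379 without the 3 deepest libraries, and it ranged from -2.43 without culture 11 to 1.456 without culture 12. For SIRE_RS00345 it became 0.4534 with total counts, 0.9824 without the 4 h libraries of cultures 11 and 12 and 0.9346 without the 3 deepest libraries, and it ranged from -2.012 without culture 11 to 1.057 without culture 12. The positive values were not called, with adjusted p from 0.1443 to 0.9771, but both falls without culture 11 were, with adjusted p of 0.01542 and 0.02583.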

Other observations

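The most abundant gene row, the third row of the table by abundance, took a larger part of the counts late in the time course, 6.727% ± 2.369 at 2.5 h, 6.458% ± 4.19 at 4 h and 12.99% ± 6.915 at 6 h (SD, n = 15 each). Relative to the median gene its difference between 2.5 h and 6 h did not pass the test (log2 0.27, edgeR adjusted p = 0.2424, upward in 8 of 15 cultures), and it rose from 4 h to 6 h (log2 0.55, adjusted p = 0.0307, 13 of 15 cultures).

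A different abundant gene, the sixth row by abundance, rose in every culture at each step. It held 0.1895% ± 0.06409 of the counts at 2.5 h, 0.4588% ± 0.3629 at 4 h and 1.595% ± 1.067 at 6 h (SD, n = 15 each). Relative to the median gene the rise from 2.5 h to 6 h was 5.083-fold (log2 2.35, standard error 0.2052, edgeR adjusted p = 3.572e-12), with 2.032-fold by 4 h (adjusted p = 0.0001178) and 2.501-fold from 4 h to 6 h (adjusted p = 9.143e-06). Both rows were singled out by abundance after their values were seen.

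The tests chosen only after the result was seen were the covariate test of the share, both tests on cultures 11 and 12, and all 3 tests on neighbouring genes. The thinning outside the 2 abundant rows was also chosen after the data were seen, as was the split of the cultures by number.

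Regrouping of the libraries did not give counts as large as the real ones. In each of 14 sets of 100 splits, the real one included, only 1 split, the real one, gave as many genes. Such splits ask whether the time point matters at all, and they do not show that each count has the right size. When time labels were exchanged within cultures, the highest other counts were 454 against the real 814 for 4 h against 2.5 h, 187 against 709 for 6 h against 4 h, 904 against 1395 for 6 h against 2.5 h, 179 against 1553 over the 3 time points, and 1, 0 and 0 against 71, 25 and 61 for peaks at 2.5 h, 4 h and 6 h. When labels were drawn over all libraries, the highest others were 117, 89, 353 and 72 for those 4 counts and 19, 0 and 4 for the peaks. The split with 904 genes exchanged the labels of 2 of the 15 cultures, the fewest drawn for that comparison, and so stayed close to the real split, while the one with 454 exchanged 5.

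Libraries with a low share of the 2 abundant non-coding RNA rows lay farther along the 2.5 h to 6 h axis at 6 h (Pearson r = -0.757, permutation p = 0.00117, adjusted p = 0.00702; Spearman rho = -0.7, p = 0.00457, adjusted p = 0.0274; r = -0.638 without the 2 libraries farthest from the median share; n = 15, 6 correlations computed). Among the 10 cultures numbered up to 12 the relation was unresolved. There r was -0.0147 (permutation p = 0.968) and rho -0.394 (permutation p = 0.263), but r was -0.848 without the 2 libraries farthest from the median share. The other 5 cultures combined shares of 20.33% to 52.52% with positions of 0.832 to 1.53. The batch of each culture was not used here, so a difference between batches stays open. At 4 h r was -0.694 (p = 0.00342, adjusted p = 0.0103) and rho -0.561 (p = 0.0331, adjusted p = 0.0993). That relation rested on the libraries of cultures 20 and 21, which had shares of 45.85% and 36.31% and positions of 1.15 and 0.998: among the other 13, r was -0.432 (p = 0.14) and rho -0.33. At 2.5 h r was -0.196 (p = 0.486) and rho -0.075 (p = 0.791). With total counts in place of the share, r was between -0.156 and 0.292 at the 3 time points, with adjusted p of at least 0.586. Total counts include the 2 abundant rows, and no correlation was computed with the counts outside them. Whether depth for the other genes goes with position was therefore not tested.

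The change from 2.5 h to 6 h goes with a fall of this share, which may reflect how well ribosomal RNA was depleted, a change in the RNA of the cells, or both. The share as the whole cause for this comparison is argued against by the 837 rows called with it as a covariate, 650 of them among the 1395 called without it, where the highest of 99 other splits within cultures, fitted the same way, gave 274; that bound replaced the 904 of the splits without the covariate, which 837 would not have passed, so the argument is weak. From 4 h to 6 h, the step in which the share fell by 20.8 points, the covariate kept only 246 of 709 calls and ended those of both named rises. All 814 calls from 2.5 h to 4 h were kept, but there the share changed by only -2.57 points on average. In the later step share and time moved together, so the covariate can remove change linked to time whatever its cause. The lost calls therefore cannot tell the share from time, and the share stays open as the source of much of the later change. Unequal depth as the whole cause of the change from 2.5 h to 6 h is argued against by the 786 rows called once the counts outside the 2 rows were equal in every library, 773 of them among the 1395 called at full depth. The same thinning called 319 rows against 814 for 4 h against 2.5 h, and 303 against 709 for 6 h against 4 h. Both counts fall short of the part that the bound for 6 h against 2.5 h required. Depth therefore stays open for those 2 comparisons. Time since synchronization rather than cell-cycle phase stays open and cannot be told apart from it, since 0 of the 45 libraries came from unsynchronized cultures.

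At 4 h, the library numbered 12 deviated from the time-point mean in the way the libraries of culture 11 did, with correlations of 0.727 to number 11 at 2.5 h and 0.803 to number 11 at 6 h, against 0.305 and 0.102 to its own number. The pair of falling genes shows this in single values: SIRE_RS00350 was at 545 CPM in culture 11 at 2.5 h and 118 CPM at 6 h, but at 4.36 CPM in the 4 h library numbered 11 and 227 CPM in that numbered 12. An exchange of the numbers 11 and 12 at 4 h is a candidate explanation: it raised the summed correlation of same-numbered libraries by 1.91, first of 105 possible exchanges and ahead of 0.722 for the next, with a gain of 1.69 for culture 11 and only 0.222 for culture 12, and in the labels the running sample numbers follow the culture numbers at every time point except that 12 precedes 11 at 4 h. Several cultures in 1 shared expression state stay possible, since the 4 h library numbered 12 also had a correlation of 0.488 with culture 5 at 2.5 h, between the bounds set for that explanation. The counts of called rows without a block do not use the culture numbers, while the paired tests and the directions per culture do.

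Neighbouring genes changed together between 2.5 h and 6 h, which may in part reflect co-transcription of adjacent genes. Units of up to 10 genes do not account for all of it: changes 10 places apart still had a correlation of 0.0678, above the 95% range of orders in which blocks of 10 genes were shuffled (up to 0.0488), although the most extreme running median over 51 genes, 0.533 in log2, did not exceed their 95% point of 0.545 (p = 0.0669). A trend of fold change with expression level is argued against, since the correlation of adjacent genes was 0.534 after the trend was removed and shuffled orders reached 0.0372. Gene dosage during replication predicted a positive correlation of the changes from 2.5 h to 4 h between genes 50 and 100 places apart. The values were 0.0151 and 0.00903, within the shuffled range. For 6 h against 2.5 h they were 0.0109 and 0.0128, also within it. The prediction does not cover that comparison, which sets cultures enriched in cells after S phase against cultures enriched in cells before it. A dosage effect much smaller than the changes of single genes would go unseen, so these values do not exclude gene dosage. Longer transcription units and clusters of genes under shared control stay open, since an operon map was not used here.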
